A study of Homo sapiens with 21 samples.

How the data were processed

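RNA from primary human dermal fibroblasts was sequenced in 21 libraries, 3 in each of 7 groups. Per the labels' protocols, cells were shipped, irradiated at 4.0 Gy with silicon, iron or hydrogen ions or with gamma rays from a caesium source, shipped back and rested for 13 days; a shipped, unirradiated control was kept for the charged particles and another for gamma rays, and a further group of low passage cells was neither shipped nor irradiated. Below, these groups are called the particle control, the gamma control and the low passage cells. The labels give 1 batch for all libraries. Total RNA was extracted with TRIzol and a column DNase step, depleted of ribosomal RNA, made into stranded TruSeq libraries and sequenced in pairs on a NovaSeq X, per the labels' protocols.

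The deposited table holds raw counts of read pairs per Ensembl gene, with no normalization, per the file headers. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic and aligned with HISAT2 2.0.5 to GRCh38. The counts were made with featureCounts 2.0.3 per the file headers, and with version 1.5.0 per the submitters' processing notes; the file headers record a minimum mapping quality of 10, strand setting 2 (reverse stranded) and Ensembl release 106. The table lists 61552 genes, of which 61399 were matched by identifier to a symbol and 58352 to a biotype in GENCODE release 29; 73 symbols belong to several identifiers, which were kept apart. Coordinates are those of the table, on GRCh38. The library totals ran from 19296278 to 31765168 counts, 31778 genes had a count in any library, and no pair of libraries was identical.

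Tests were computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (16090 genes), libraries were scaled by TMM factors, and 1 fit of all 21 libraries with a mean per group was tested by robust quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment within each of 13 contrasts; a gene was called at an adjusted p under 0.05. Every adjusted p given for a gene is from this test. Its p-values measure only the spread between these libraries, and nothing in the labels shows that the libraries of a group are more than replicate cultures. CPM values use the TMM-scaled library totals, and log2 changes carry the standard error of the fit. The contrasts compare each radiation with its own control, the ions with each other, the gamma effect with each ion effect, and the controls with each other. The ion and gamma effects have separate controls, so their difference is the difference of 2 changes.

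Lists of 522 gene names, of which 521 were found in the table, were written for 20 pathways and 7 cell types and tested by camera in limma 3.58.1 with a preset correlation of 0.01, two-sided and adjusted over the lists of a contrast. The pathway lists are p53 target genes, DNA replication and G1/S genes, G2/M and mitosis genes, replication-dependent histone genes, homologous recombination and Fanconi genes, end joining and damage signalling genes, nuclear lamina and chromatin genes lost in senescence, secretory cytokine and chemokine genes, secreted protease and inhibitor genes, secreted growth factor and IGF-binding genes, interferon-stimulated genes, collagen and matrix genes, contractile myofibroblast genes, lysosome genes, cholesterol synthesis genes, unfolded protein and amino acid response genes, oxidative stress response genes, immediate early genes, heat shock genes and mitochondrially encoded genes. The cell type lists hold markers of fibroblasts, keratinocytes, melanocytes, endothelial cells, pericytes and smooth muscle, leukocytes and adipocytes. Each call was repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way without comparing them with other genes. No list test used GC offsets.

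Genes are named by a rule, and some that it picks are left out for length. For each radiation against its control these are the 6 largest rises and 6 largest falls among called protein-coding genes with at least 5 CPM in the higher group and no overlap between the libraries compared, 14 preset genes of cell cycle arrest and secretion, and the 3 members with the smallest p of every list past the threshold; for the other contrasts, 5 rises, 5 falls and 2 members per list. Genes called the same way by all 4 radiations add the 5 with the highest and the 5 with the lowest mean change. A set of 33 genes that people commonly lack or carry in extra copies was left out, and 3 of the genes the rule picks are for that reason not reported, nor are genes that differ by sex. A few further genes are not reported here. The groups, contrasts, lists, naming rule and other alternatives were fixed before the data were examined. A correction for GC content (offsets per library from 20 bins of GC), the fits with 1 control library per ion and most tests of technical causes and other splits were chosen after seeing the data.

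The strand setting separates antisense genes, but genes that overlap on 1 strand share reads that the counting could not place: of the genes in the report, C1R shares 11.6% of its exon length with another gene, ACTA2 13.5%, PDGFRA 16.1%, RGS5 8.06% and IFI6 23.1%. Members of near-identical families, such as the replication-dependent histones and the actins ACTA2, ACTG2 and ACTC1, lose read pairs that align equally well to several copies, so their levels are uncertain. The mitochondrial share of counts served as a sign of sample quality.

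The edgeR steps were tested on simulated counts drawn from the means and totals of these libraries with known changes. In silicon against its control, 67.3% of genes changed 1.5-fold and 70.1% of those changed 2-fold were recovered among 15651 genes, with 6 unchanged genes called. For gamma against its control the shares were 66.3% and 82.0%, with 5 unchanged genes called. The alternatives tried were DESeq2 size factors, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the sample number as a replicate block, another control, leaving out each library in turn, and the GC offsets. For the overlap of calls, a 2-fold minimum was also tried. Depth was tested by thinning every library to 19296278 counts. Tables used the R package data.table in version 1.17.8, and figures Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.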

Results

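RNA levels in primary human dermal fibroblasts were measured 13 days after return from irradiation, in 3 libraries for each of 7 groups. The charged particles differ in energy and in linear energy transfer, which is the energy left per length of track. Silicon had 238 MeV/n and 79 keV/µm, iron 600 MeV/n and 174 keV/µm, and hydrogen 150 MeV/n and 0.5 keV/µm. Library totals ran from 23284889 to 27423832 counts in the particle control, 23561747 to 25476492 in silicon, 22080400 to 27511013 in iron and 25078269 to 31765168 in hydrogen. They ran from 25402698 to 28451513 in the gamma control, 25259463 to 27503971 in gamma and 19296278 to 26141625 in the low passage cells. The first 3 principal components of log2 CPM held 61.0%, 26.7% and 4.85% of the variance. The comparisons ask which genes each radiation changed after a rest in which senescence was to develop, and how far the effects differ. Positions of genes are on GRCh38.

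**Figure D1:**
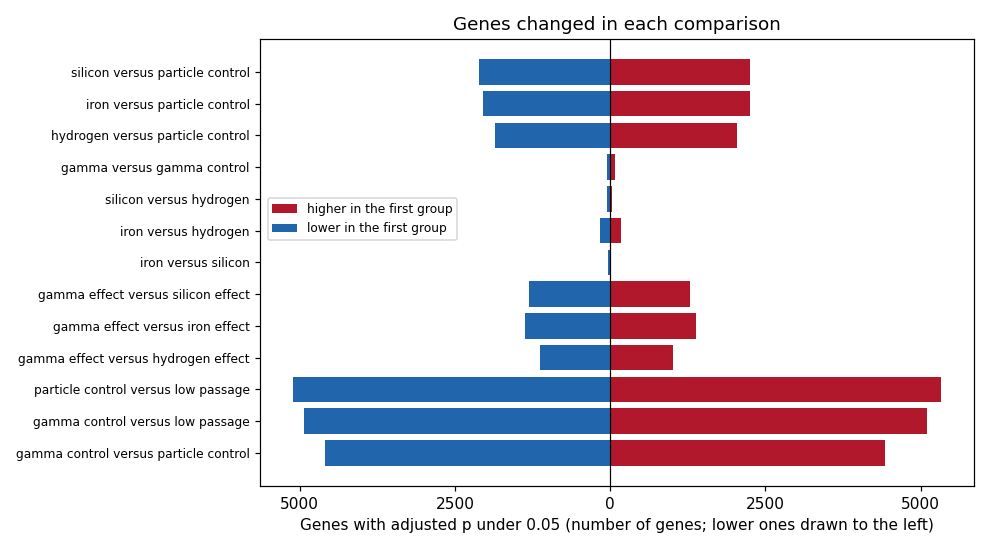
Genes called in each of the 13 comparisons (edgeR, adjusted p under 0.05). The horizontal axis counts genes, higher in the first group to the right and lower to the left, and each bar is 1 comparison. Gamma against its control has 82 higher and 49 lower. Silicon has 2250 and 2110, iron 2254 and 2041, and hydrogen 2046 and 1860.

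The first comparison asks what silicon ions changed. MMP10 (stromelysin-2, ENSG00000166670, chromosome 11, 102770502 to 102780628) rose from 1.83 ± 0.595 to 35.2 ± 1.66 CPM (SD, n = 3). Its neighbours MMP1 (interstitial collagenase, ENSG00000196611, chromosome 11, 102789401 to 102798160) and MMP3 (stromelysin-1, ENSG00000149968, chromosome 11, 102835801 to 102843609), which cleave matrix proteins, rose from 2.67 ± 0.327 to 36.5 ± 1.16 and from 37.2 ± 1.73 to 230.3 ± 3.63 CPM. ACAN (aggrecan, a large proteoglycan of cartilage, ENSG00000157766, chromosome 15, 88803436 to 88875353) fell from 213 ± 12.7 to 2.73 ± 0.479 CPM, a log2 change of -6.29 ± 0.10 (SE). ACTC1 (cardiac alpha actin, ENSG00000159251, chromosome 15, 34790230 to 34795549) fell from 431 ± 7.62 to 66.9 ± 0.964 CPM. ACTA2 (smooth muscle actin, the usual mark of the myofibroblast, ENSG00000107796, chromosome 10, 88935074 to 88991339) fell from 2159 ± 29.5 to 819.6 ± 20.2 CPM. CDH10 (a cadherin), KCTD4 (a potassium channel domain protein) and CD24 (a surface glycoprotein) rose by 2.59, 2.48 and 2.45 (log2, SE up to 0.22). ITGA8 (an integrin), SORBS2 (an actin adaptor), COLEC12 (a scavenger receptor) and C1R (a complement protease) changed by -2.96, -2.71, -2.65 and -2.55 (log2, SE up to 0.18). EdgeR gave each of these genes an adjusted p of 1.8e-10 or less.

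Marks of arrest and secretion went several ways under silicon. CDKN1A (p21, which halts the cell cycle) was lower, at 1799 ± 49.9 against 2194 ± 47.8 CPM (SD, n = 3). CDKN2A (p16 and ARF) was higher, at 17.1 ± 1.54 against 12 ± 0.457 CPM. MKI67 (a proliferation antigen) fell from 1.57 ± 0.323 to 0.443 ± 0.111 CPM and LMNB1 (lamin B1, lost in senescent nuclei) from 1.96 ± 0.233 to 1.03 ± 0.124 CPM, so the control expressed little of either. GDF15 (a stress cytokine), IL6 and COL1A1 (type I collagen) changed by 0.98, 0.39 and -0.68 (log2, SE up to 0.13). CXCL8 (interleukin 8) rose but stayed under 1 CPM, at 0.811 ± 0.184 against 0.172 ± 0.0350. HMGB2 (a chromatin protein) and CDKN2B (p15) changed by -0.10 and 0.18 and were not called, with an edgeR adjusted p of 0.0517 for CDKN2B.

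Contractile myofibroblast genes moved down (camera adjusted p = 1.24e-18). Of 18 genes, 17 fell, and 17 fell adjusted over the list alone. LMOD1 (leiomodin, an actin nucleator) fell from 304 ± 11.4 to 152 ± 3.41 CPM (SD, n = 3) and ACTG2 (enteric actin) from 563 ± 15.3 to 291 ± 5.42 CPM. By camera, secreted protease and inhibitor genes moved up (adjusted p = 1.57e-13). Of 19 genes, 15 rose and 2 fell, and 15 rose and 2 fell adjusted over the list alone. SERPINE2 (protease nexin 1, ENSG00000135919, chromosome 2, 223975045 to 224039318) rose from 578 ± 2.18 to 1983 ± 52.0 CPM. Cholesterol synthesis genes moved up (camera adjusted p = 2.74e-06). Of 21 genes, 13 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. MSMO1 and HMGCS1 rose by 0.67 and 0.55 (log2, SE up to 0.07). By camera, replication-dependent histone genes moved up (adjusted p = 0.000234). Of 9 genes, 6 rose, and 7 rose adjusted over the list alone. H1-2 and H4C8 rose by 0.68 and 1.05 (log2, SE up to 0.09). G2/M and mitosis genes moved down (camera adjusted p = 3.05e-05). Of 29 genes, 1 rose and 19 fell, and 1 rose and 22 fell adjusted over the list alone. FOXM1 and ASPM changed by -1.48 and -1.35 (log2, SE up to 0.18). Of 11 lists past the threshold of camera, 5 held with an estimated correlation.

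By camera, collagen and matrix genes moved down (adjusted p = 7.34e-07, adjusted p = 0.116 with an estimated correlation). Of 30 genes, 5 rose and 18 fell, and 5 rose and 19 fell adjusted over the list alone. COL15A1 (a basement membrane collagen), THBS2 (thrombospondin 2) and LOX (which cross-links collagen) changed by -1.49, -0.66 and 0.70 (log2, SE up to 0.08). Lysosome genes moved up (camera adjusted p = 0.005, adjusted p = 0.116 with an estimated correlation). NPC2, FUCA1 and GLB1 rose by 0.55, 0.56 and 0.45 (log2, SE up to 0.07). By camera, unfolded protein and amino acid response genes moved up (adjusted p = 0.0128, adjusted p = 0.05 with an estimated correlation). PHGDH, PSAT1 (like PHGDH an enzyme of serine synthesis) and SLC7A11 (a cystine carrier) changed by -1.59, -0.69 and 0.62 (log2, SE up to 0.07). Mitochondrially encoded genes moved up (camera adjusted p = 0.00191, adjusted p = 0.358 with an estimated correlation). Of 13 genes, 5 rose, and 8 rose adjusted over the list alone. MT-CO2, MT-CO3 and MT-ND1 rose by 0.34, 0.28 and 0.52 (log2, SE up to 0.12). Mitochondrial genes held 4.93 ± 0.169% of counts (SD, n = 3) in silicon against 4.12 ± 0.0590% in the control. By camera, fibroblast markers moved down (adjusted p = 0.0382, adjusted p = 0.0847 with an estimated correlation). PDGFRA, FBLN1 and DCN changed by 1.11, -1.49 and -0.96 (log2, SE up to 0.07). Pericyte and smooth muscle markers moved down (camera adjusted p = 0.0382, adjusted p = 0.116 with an estimated correlation). RGS5, MCAM and KCNJ8 changed by 2.35, -0.90 and -0.67 (log2, SE up to 0.10).

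The other lists did not pass camera under silicon. The brackets give how many members rose and fell, the same adjusted over the list alone, and the adjusted p of camera. Among genes of DNA damage they were p53 target genes (6 and 7 of 30, 7 and 7, adjusted p = 0.882, median of -0.018, mean of 0.014), homologous recombination and Fanconi genes (1 and 2 of 22, 1 and 2, adjusted p = 0.444) and end joining and damage signalling genes (2 and 1 of 20, 2 and 1, adjusted p = 0.719). Cell cycle lists short of the camera threshold were DNA replication and G1/S genes (1 and 6 of 30, 1 and 5, adjusted p = 0.233) and nuclear lamina and chromatin genes lost in senescence (1 and 5 of 15, 1 and 5, adjusted p = 0.285). Of secreted factors, camera gave secretory cytokine and chemokine genes (8 and 2 of 18, 9 and 2, adjusted p = 0.0839) and secreted growth factor and IGF-binding genes (11 and 7 of 25, 11 and 7, adjusted p = 0.233, median of -0.030, mean of 0.21). Stress lists by camera were interferon-stimulated genes (2 and 3 of 22, 2 and 3, adjusted p = 0.334), oxidative stress response genes (6 and 4 of 19, 7 and 4, adjusted p = 0.445), immediate early genes (3 and 6 of 16, 4 and 6, adjusted p = 0.444, median of 0.041, mean of -0.054) and heat shock genes (3 and 3 of 12, 5 and 3, adjusted p = 0.82, median of 0.081, mean of -0.006). Markers of other cells by camera were keratinocyte markers (2 and 1 of 7, 2 and 1, adjusted p = 0.615), melanocyte markers (1 and 0 of 2, 1 and 0, adjusted p = 0.719, median of -0.18, mean of -0.18), endothelial markers (1 and 0 of 5, 1 and 0, adjusted p = 0.233) and leukocyte markers (1 and 0 of 3, 1 and 0, adjusted p = 0.183). The adipocyte list kept 1 measured gene and was not tested.

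In all, edgeR called 2250 genes higher and 2110 lower in silicon than in the particle control, of 16090 tested. Of these, 771 changed by 2-fold or more. The choice of control decides many directions. Against the gamma control the log2 change was -2.47 for MMP1, 1.20 for CDKN1A and -2.63 for IL6. Against the low passage cells these were -2.87, 1.94 and -2.73, and ACTA2 changed by 0.82. These controls gave 10057 and 10555 calls. With libraries named by group and number, calls ended without particle control 3 for IL6 (0.39), and silicon 1 for IL6 (0.29). A fit of only these groups ended the call of IL6. CDKN2B was called without silicon replicate 1 (0.23).

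Iron ions had the highest linear energy transfer. MMP10 rose from 1.83 ± 0.595 to 29.2 ± 3.59 CPM (SD, n = 3) and MMP1 from 2.67 ± 0.327 to 33.1 ± 2.70 CPM, while ACAN fell from 213 ± 12.7 to 2.40 ± 0.240 CPM. SFRP1 (a secreted antagonist of Wnt signals, ENSG00000104332, chromosome 8, 41261962 to 41309473) rose from 5.52 ± 0.217 to 29.3 ± 1.95 CPM. ACTC1 fell from 431 ± 7.62 to 56.7 ± 1.53 CPM. CDH10, SORBS2, ITGA8, C1R and NIPAL4 (a magnesium carrier) changed by 2.57, -2.76, -2.75, -2.70 and -2.61 (log2, SE up to 0.18). None of these genes had an edgeR adjusted p above 2.89e-13.

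CDKN1A, LMNB1, MKI67 and COL1A1 changed by -0.21, -1.05, -2.0 and -0.62 (log2, SE up to 0.27). CDKN2A, GDF15, IL6 and MMP3 rose by 0.60, 1.13, 0.71 and 2.32 (log2, SE up to 0.12). CXCL8 rose to 0.545 ± 0.231 CPM (SD, n = 3). HMGB2 and CDKN2B were not called under iron, with an edgeR adjusted p of 0.107 for HMGB2. By camera, contractile myofibroblast genes moved down (adjusted p = 5.67e-17). ACTA2, LMOD1 and ITGA11 (a collagen-binding integrin) changed by -1.31, -0.94 and -0.88 (log2, SE up to 0.06). Secreted protease and inhibitor genes moved up (camera adjusted p = 2.66e-13). SERPINE2 rose by 1.66 (log2, SE 0.05). By camera, cholesterol synthesis genes moved up (adjusted p = 1.4e-06). MSMO1 and FDFT1 rose by 0.58 and 0.41 (log2, SE up to 0.06). Replication-dependent histone genes moved up (camera adjusted p = 0.00021). H1-2 and H4C8 rose by 0.80 and 1.0 (log2, SE up to 0.09). By camera, G2/M and mitosis genes moved down (adjusted p = 9.01e-06). FOXM1 and ASPM changed by -2.18 and -1.15 (log2, SE up to 0.20). Of 9 lists past the threshold of camera, 5 held with an estimated correlation.

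Collagen and matrix genes moved down (camera adjusted p = 1.85e-07, adjusted p = 0.121 with an estimated correlation). COL15A1, THBS1 and LOX changed by -1.42, -0.63 and 0.65 (log2, SE up to 0.08). By camera, lysosome genes moved up (adjusted p = 0.00154, adjusted p = 0.0919 with an estimated correlation). NPC2 and CTSL rose by 0.59 and 0.44 (log2, SE up to 0.06). Mitochondrially encoded genes moved up (camera adjusted p = 0.00106, adjusted p = 0.34 with an estimated correlation). Mitochondrial genes held 4.84 ± 0.185% of counts (SD, n = 3) in iron. By camera, fibroblast markers moved down (adjusted p = 0.0401, adjusted p = 0.0882 with an estimated correlation). EdgeR called 2254 genes higher and 2041 lower under iron, 766 by 2-fold or more. With the gamma control or the low passage cells in place of the particle control, MMP1 changed by -2.62 and -3.01. CDKN1A then changed by 1.28 and 2.02, and 9832 and 10600 genes were called. Iron 1 stood apart, with a chi-square per gene of 6.94 and 5.57 against iron 2 and 3, and 2.05 between those. Without it 3598 genes were called. Calls ended without particle control 1 for CDKN1A (-0.19), particle control 3 for CDKN1A (-0.19), iron 2 for CDKN1A (-0.18) and CXCL8 (1.29), and iron 3 for CDKN1A (-0.18).

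Hydrogen ions were compared with the same particle control, at a low linear energy transfer. MMP10 rose from 1.83 ± 0.595 to 26.6 ± 0.885 CPM (SD, n = 3), MMP1 from 2.67 ± 0.327 to 28.8 ± 1.11 CPM and MMP3 from 37.2 ± 1.73 to 192 ± 8.70 CPM. ESM1 (endocan, a secreted proteoglycan, ENSG00000164283, chromosome 5, 54977867 to 55022671) rose from 4.17 ± 0.557 to 18.4 ± 1.31 CPM. ACAN fell from 213 ± 12.7 to 6.79 ± 0.705 CPM and ACTC1 from 431 ± 7.62 to 83.0 ± 4.88 CPM. CD24 and CDH10 rose by 2.08 and 2.10 (log2, SE up to 0.17). SORBS2, ITGA8, C1R and PEAR1 (a receptor of platelets) changed by -2.46, -2.29, -2.09 and -1.98 (log2, SE up to 0.18). Their edgeR adjusted p was at most 2.57e-11.

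Secreted factors also changed under hydrogen. LIF (a cytokine of the IL6 family) rose from 2.92 ± 0.506 to 10.2 ± 1.25 CPM (SD, n = 3), CCL2 (a chemokine for monocytes) from 28.8 ± 0.472 to 60.8 ± 2.25 CPM and IGFBP2 (an IGF-binding protein) from 15.5 ± 1.77 to 51.0 ± 5.91 CPM. CXCL12 (another chemokine) fell from 64.4 ± 1.32 to 32.5 ± 2.11 CPM. Secretory cytokine and chemokine genes moved up (camera adjusted p = 0.0215, adjusted p = 0.0569 with an estimated correlation). By camera, secreted growth factor and IGF-binding genes moved up (adjusted p = 0.0215, adjusted p = 0.0658 with an estimated correlation). ANGPTL4 and STC2 rose by 1.54 and 0.69 (log2, SE up to 0.12). CDKN1A, LMNB1, MKI67 and COL1A1 changed by -0.39, -1.05, -1.08 and -0.75 (log2, SE up to 0.23). CDKN2A, GDF15 and IL6 rose by 0.33, 0.65 and 0.81 (log2, SE up to 0.12). CXCL8 rose to 0.513 ± 0.162 CPM. HMGB2 and CDKN2B were not called under hydrogen, with an edgeR adjusted p of 0.174 for CDKN2B.

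Contractile myofibroblast genes moved down (camera adjusted p = 1.81e-18). ACTA2, ACTG2 and LMOD1 changed by -1.30, -0.92 and -0.83 (log2, SE up to 0.06). By camera, secreted protease and inhibitor genes moved up (adjusted p = 1.97e-12). SERPINE2 rose by 1.52 (log2, SE 0.05). Cholesterol synthesis genes moved up (camera adjusted p = 8.63e-06). MSMO1 and HMGCS1 rose by 0.62 and 0.52 (log2, SE up to 0.07). By camera, replication-dependent histone genes moved up (adjusted p = 0.00433). H1-2, H4C8 and H3C10 rose by 0.61, 0.93 and 0.75 (log2, SE up to 0.24). Of 11 lists past the threshold of camera, 4 held with an estimated correlation. G2/M and mitosis genes moved down (camera adjusted p = 0.00228, adjusted p = 0.118 with an estimated correlation). FOXM1, PLK1 and KIF2C changed by -1.27, -1.24 and -0.77 (log2, SE up to 0.23). By camera, collagen and matrix genes moved down (adjusted p = 6.47e-06, adjusted p = 0.179 with an estimated correlation). LOX, POSTN (periostin) and COL15A1 changed by 0.54, 0.88 and -0.82 (log2, SE up to 0.07). Lysosome genes moved up (camera adjusted p = 0.0264, adjusted p = 0.202 with an estimated correlation).

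By camera, mitochondrially encoded genes moved up (adjusted p = 0.000341, adjusted p = 0.303 with an estimated correlation). MT-CO2, MT-ND3 and MT-ND2 rose by 0.32, 0.37 and 0.50 (log2, SE up to 0.11). Mitochondrial genes held 4.97 ± 0.489% of counts (SD, n = 3) in hydrogen. Pericyte and smooth muscle markers moved down (camera adjusted p = 0.0369, adjusted p = 0.155 with an estimated correlation). EdgeR called 2046 genes higher and 1860 lower under hydrogen, 557 by 2-fold or more. Log2 changes ran against GC content across genes, which are not independent (rho = -0.378). With the gamma control or the low passage cells as control, MMP1 changed by -2.81 and -3.21, and 10087 and 10573 genes were called. Hydrogen 3 stood apart, with a chi-square per gene of 12.5 and 12.2 against hydrogen 1 and 2, and 2.11 between those. Its mitochondrial share was 4.42% against 5.33% and 5.17%. Without it 4312 genes were called. Calls ended without particle control 2 for CXCL8 (1.42) and H3C10 (0.68), hydrogen 2 for CXCL8 (1.46), and hydrogen 3 for CXCL8 (1.42) and H3C10 (0.64).

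**Figure D2:**
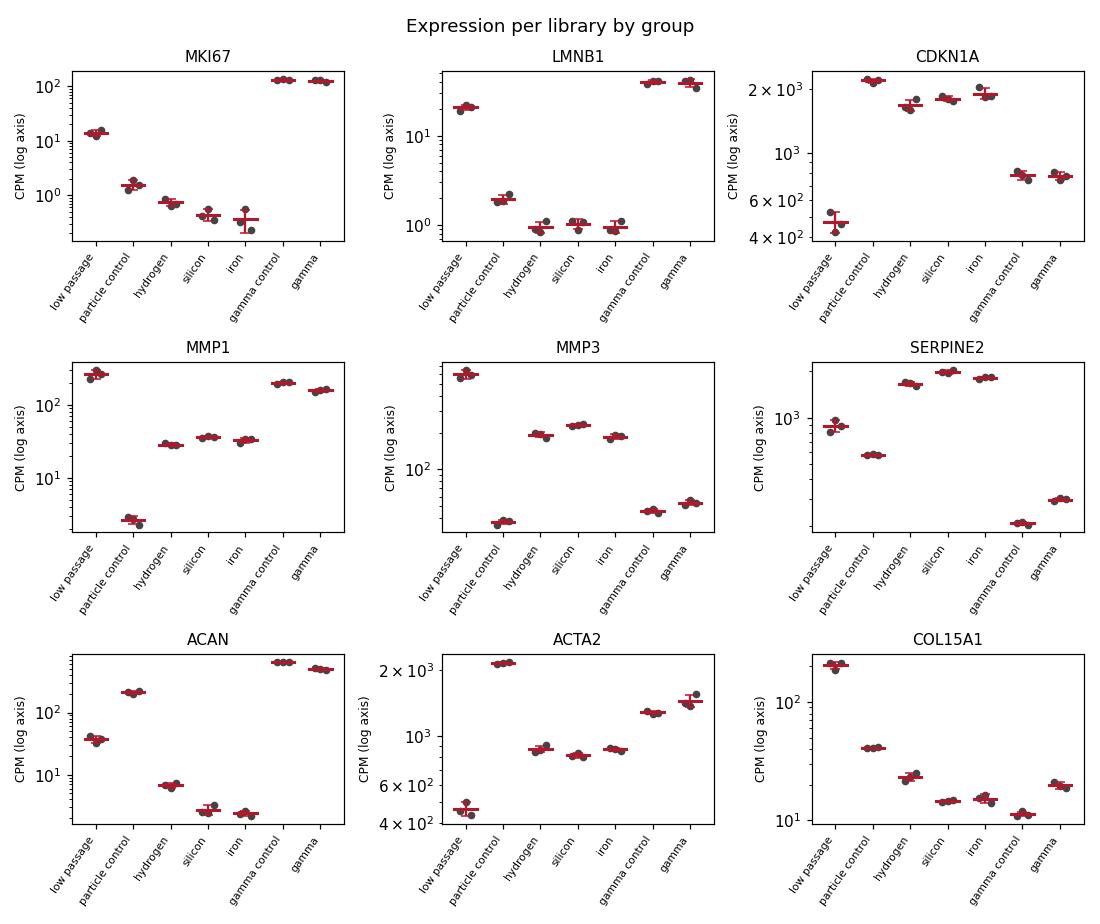
CPM of 9 genes in each library, on a log axis, for the 7 groups. Points are libraries, the red bar is the mean and the error bar the SD (n = 3). ACAN lies at 2.73, 2.40 and 6.79 CPM in silicon, iron and hydrogen against 213 in the particle control. MKI67 lies at 132 CPM in the gamma control and 1.57 in the particle control.

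Gamma rays were compared with their own shipped control. TGFBI (a matrix protein induced by TGF-beta, ENSG00000120708, chromosome 5, 136028988 to 136063818) rose from 1331 ± 34.2 to 2205 ± 3.01 CPM (SD, n = 3). HAPLN1 (which links hyaluronan to proteoglycan, ENSG00000145681, chromosome 5, 83637805 to 83720855) rose from 7.84 ± 0.289 to 15.8 ± 0.269 CPM and COL15A1 from 11.4 ± 0.505 to 19.8 ± 1.29 CPM. ITIH5 (an inhibitor that binds hyaluronan, ENSG00000123243, chromosome 10, 7559270 to 7666998) fell from 14.7 ± 0.372 to 6.63 ± 1.08 CPM and WNT2 (a secreted Wnt ligand) from 31.4 ± 0.638 to 17.3 ± 0.575 CPM. COMP (a cartilage matrix protein), ATF3 (a stress transcription factor) and EPB41L3 (a membrane skeleton protein) rose by 0.99, 0.89 and 1.25 (log2, SE up to 0.26). SIX2, FOXL2NB, TMTC1 and TNFRSF19 changed by -0.96, -0.80, -0.73 and -0.68 (log2, SE up to 0.13). These genes had an edgeR adjusted p of up to 0.0117.

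Of the 14 preset genes, IL6 rose from 24.1 ± 0.339 to 36.7 ± 0.871 CPM (SD, n = 3) and MMP1 fell from 203 ± 5.61 to 160.4 ± 7.39 CPM under gamma. CDKN1A was at 775 ± 33.7 against 782 ± 38.7 CPM, MKI67 at 126 ± 6.86 against 132 ± 5.72 and LMNB1 at 39.4 ± 4.40 against 40.1 ± 1.79, so both groups of the gamma arm expressed proliferation genes. MMP3, COL1A1, GDF15, CDKN2A and CDKN2B changed by 0.23, 0.18, 0.07, 0.11 and 0.18. None of these, nor HMGB2 and CXCL8, was called, the smallest edgeR adjusted p being 0.0745 for MMP3.

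By camera, collagen and matrix genes moved up (adjusted p = 1.84e-16). Of 30 genes, 6 rose, and 15 rose and 1 fell adjusted over the list alone. TNC (tenascin C) and VCAN (versican) rose by 0.44 and 0.47 (log2, SE up to 0.08). Secreted protease and inhibitor genes moved up (camera adjusted p = 0.000209). Of 19 genes, 3 rose and 1 fell, and 8 rose and 4 fell adjusted over the list alone. MMP2, SERPINE2 and TIMP3 rose by 0.58, 0.51 and 0.27 (log2, SE up to 0.06). By camera, unfolded protein and amino acid response genes moved up (adjusted p = 1.42e-10). Of 20 genes, 5 rose, and 11 rose and 1 fell adjusted over the list alone. PSAT1 and PHGDH rose by 0.50 and 0.38 (log2, SE up to 0.07). Immediate early genes moved up (camera adjusted p = 2.6e-09). Of 16 genes, 2 rose, and 8 rose adjusted over the list alone. EGR1, ZFP36 and DUSP1 changed by 0.59, 0.44 and 0.16 (log2, SE up to 0.11), with DUSP1 not called. By camera, fibroblast markers moved up (adjusted p = 0.000395). Of 14 genes, 2 rose, and 4 rose adjusted over the list alone. FAP, MFAP5 and PDGFRA changed by 0.32, 0.33 and 0.23 (log2, SE up to 0.07), with PDGFRA not called. Secretory cytokine and chemokine genes moved up (camera adjusted p = 0.0294), against a median of 0.092 and a mean of -0.029. Of 18 genes, 1 rose, and 3 rose adjusted over the list alone. LIF and CXCL12 changed by 0.46 and 0.15 (log2, SE up to 0.13), neither of them called.

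By camera, G2/M and mitosis genes moved down (adjusted p = 1.22e-11). In edgeR 0 of 29 genes passed, and 0 adjusted over the list alone, while 6 lay at an unadjusted p under 0.05 and 0 passed in DESeq2. ASPM, PLK1 and AURKA changed by -0.20, -0.23 and -0.20 (log2, SE up to 0.09), not called. DNA replication and G1/S genes moved down (camera adjusted p = 0.000118). In edgeR 0 of 30 genes passed, and 0 adjusted over the list alone, while 5 lay at an unadjusted p under 0.05 and 0 passed in DESeq2. RRM2, CCNE1 and TYMS changed by -0.20, -0.27 and -0.15 (log2, SE up to 0.11), not called. By camera, nuclear lamina and chromatin genes lost in senescence moved down (adjusted p = 0.00655, adjusted p = 0.0674 with an estimated correlation). In edgeR 0 of 15 genes passed, and 0 adjusted over the list alone, while 0 lay at an unadjusted p under 0.05 and 0 passed in DESeq2. LMNB2, CBX5 and HMGB3 changed by -0.17, -0.11 and -0.15 (log2, SE up to 0.09), not called. Pericyte and smooth muscle markers moved down (camera adjusted p = 0.00736). In edgeR 0 of 7 genes passed, 1 fell adjusted over the list alone, while 3 lay at an unadjusted p under 0.05 and 1 passed in DESeq2. RGS5, SUSD5 and NOTCH3 changed by -0.56, -0.21 and -0.33 (log2, SE up to 0.16), not called. Of 10 lists past the threshold of camera, 9 held with an estimated correlation. EdgeR called 82 genes higher and 49 lower under gamma, 11 by 2-fold or more. At an unadjusted p under 0.05 lay 1288 genes. The count rose to 341 with GC offsets, 238 in a fit of only these groups and 203 with the DESeq2 Wald test. It was 80 without gamma control 1, 75 without gamma control 2, 81 without gamma control 3 and 83 without gamma 1. Gamma 3 stood apart, with a chi-square per gene of 9.09 and 9.23 against gamma 1 and 2, and 4.27 between those. Calls ended without gamma control 1 for EPB41L3 (1.25), ZFP36 (0.49) and FAP (0.29), gamma control 3 for EPB41L3 (1.15), MMP1 (-0.32) and ZFP36 (0.45), gamma 1 for EPB41L3 (1.22), MMP1 (-0.30) and ZFP36 (0.42), gamma 3 for EPB41L3 (1.20) and ZFP36 (0.46), gamma control 2 for MMP1 (-0.33), ZFP36 (0.41) and MFAP5 (0.32), and gamma 2 for ZFP36 (0.46). Against the particle control MMP1 changed by 5.91, MKI67 by 6.33 and ACAN by 1.25.

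**Figure D3:**
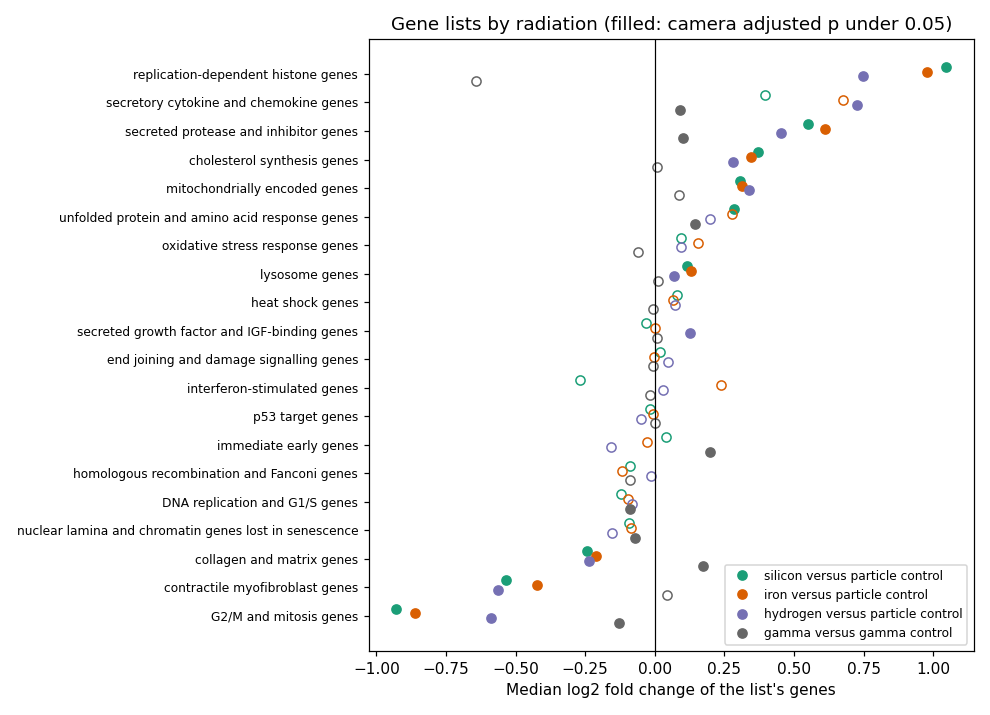
Median log2 change of the 20 pathway lists (horizontal axis) under the 4 radiations against their controls. Each point is 1 list under 1 radiation, filled where camera passed at an adjusted p under 0.05. Contractile genes lie at -0.54, -0.42 and -0.56 under silicon, iron and hydrogen, and collagen and matrix genes at 0.17 under gamma.

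Genes called the same way by all 4 radiations numbered 20 higher and 8 lower. These 28 became 78 with GC offsets and 2 with a 2-fold minimum. SERPINE2 rose by 1.78, 1.66, 1.52 and 0.51 on the log2 scale under silicon, iron, hydrogen and gamma. In that order NTM (neurotrimin, an adhesion protein, ENSG00000182667, chromosome 11, 131370478 to 132336822) rose by 1.56, 1.51, 1.42 and 0.47. HAPLN1 rose by 1.27, 1.08, 1.0 and 1.01, COMP by 0.81, 0.78, 0.61 and 0.99 and LPXN (leupaxin, a focal adhesion protein) by 1.12, 0.98, 0.99 and 0.32. ACAN changed by -6.29, -6.46, -4.98 and -0.37 and GAS1 (a growth arrest gene) by -1.32, -1.10, -0.85 and -0.42. ITIH5 changed by -0.71, -0.63, -0.55 and -1.15, ACTG2 by -0.95, -0.75, -0.92 and -0.25 and TENM2 (a teneurin, of cell adhesion) by -1.02, -0.74, -0.66 and -0.44. The SE of these values was at most 0.17, and the edgeR adjusted p under gamma at most 0.0192. Against the particle control in place of their own, gamma libraries had NTM at -1.41, SERPINE2 at -0.96 and ACAN at 1.25. Calls ended without gamma control 1 for LPXN (0.34) and ACTG2 (-0.24), gamma control 3 for LPXN (0.28) and ACTG2 (-0.27), gamma 3 for LPXN (0.25) and TENM2 (-0.38), gamma control 2 for ACTG2 (-0.24), gamma 1 for ACTG2 (-0.23), and gamma 2 for ACTG2 (-0.21).

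Among the ions, 1447 genes rose in all 3, MMP1 and MMP10 among them, and 1210 fell in all 3, ACTA2 and ACTC1 among them. These are 47.9% and 41.8% of those called under any ion. With a 2-fold minimum 386 were left. Silicon and iron shared 1754 rises and 1562 falls, all against the same control libraries. Giving each ion its own control library cannot show how far the control makes the overlap. A deviation common to the control group enters every ion effect. Silicon and gamma shared 27 rises and 12 falls, where independent lists would share 11.5 and 6.43. In opposite directions silicon and gamma called 47 genes, more than either shared count, with no such value computed, so net agreement was not shown. Gamma and iron shared 23 rises and 9 falls beside 53 opposite calls. For gamma and hydrogen these were 23, 10 and 51.

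Effects were also correlated across 9349 genes with a mean log2 CPM above 3, which are not independent. The correlation was 0.941 for silicon and iron, 0.939 for silicon and hydrogen and 0.871 for iron and hydrogen. Gamma correlated with silicon, iron and hydrogen at 0.017, -0.047 and 0.044. The ions share a control group, whose common deviation stays even with no library shared. With 1 control library per ion and none shared, correlations ran from 0.838 to 0.909, 0.838 to 0.888 and 0.740 to 0.860 in the same order.

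Silicon and hydrogen, which differ in linear energy transfer, were compared directly. SFRP1 was higher in silicon, at 28.0 ± 0.906 against 16 ± 0.611 CPM (SD, n = 3). RGS5 (a regulator of G protein signals in mural cells) was also higher, at 49.1 ± 4.11 against 30.5 ± 3.36 CPM. ALDH1A1 (a retinal dehydrogenase, ENSG00000165092, chromosome 9, 72900671 to 73080442) was lower, at 226 ± 2.18 against 409 ± 21.4 CPM, as was NTRK2 (a neurotrophin receptor), at 22.3 ± 0.860 against 41.1 ± 0.956. SOX9, PLXDC2 and PMAIP1 (NOXA) differed by 0.59, 0.53 and 0.44 (log2, SE up to 0.14). ACAN, GRIA1 (a glutamate receptor) and SASS6 (a centriole protein) differed by -1.31, -1.01 and -0.93 (log2, SE up to 0.17). EdgeR gave each of these genes an adjusted p of 0.0372 or less. Of the preset genes, MMP1 (0.34 ± 0.08) and MMP3 (0.27 ± 0.06) differed.

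By camera, secreted protease and inhibitor genes moved up (adjusted p = 9.69e-07). Of 19 genes, 5 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone. PLAU (urokinase) and TIMP3 changed by 0.43 and -0.26 (log2, SE up to 0.08). Fibroblast markers moved down (camera adjusted p = 0.000691). Of 14 genes, 1 fell, and 5 fell adjusted over the list alone. DCN and FBLN1 changed by -0.39 and -0.27 (log2, SE up to 0.07), with FBLN1 not called. By camera, interferon-stimulated genes moved down (adjusted p = 0.00106). Of 22 genes, 1 fell, and 3 fell adjusted over the list alone. SAMD9L and IFIT3 changed by -0.29 and -0.40 (log2, SE up to 0.11), with IFIT3 not called. The lists unfolded protein and amino acid response genes (adjusted p = 0.00989) and replication-dependent histone genes (adjusted p = 0.0117) passed camera upward. Lost in camera were p53 target genes (adjusted p = 0.0334, adjusted p = 0.0537 with an estimated correlation) upward and G2/M and mitosis genes (adjusted p = 0.0048, adjusted p = 0.134 with an estimated correlation) downward. Lost likewise, downward in camera, were the collagen and contractile lists (adjusted p = 0.00106 and 0.0147, with an estimated correlation 0.288 and 0.134). ASPM and COL15A1 differed by -1.01 and -0.67 (log2, SE up to 0.16). EdgeR called 27 genes higher and 56 lower in silicon, 4 by 2-fold or more. Changes followed GC content across genes (rho = 0.469). With GC offsets, not tried on lists, 225 genes were called, 82 of them shared. With no filter the count was 139, and 141 with the DESeq2 Wald test. It was 45 without silicon 1, 42 without silicon 2, 53 without silicon 3, 39 without hydrogen 1 and 52 without hydrogen 2. Calls ended without silicon 1 for SOX9 (0.50), PMAIP1 (0.44), PLAU (0.40) and SAMD9L (-0.28), silicon 2 for SOX9 (0.55) and SAMD9L (-0.30), hydrogen 1 for SOX9 (0.54), PMAIP1 (0.40) and SAMD9L (-0.25), hydrogen 2 for SOX9 (0.63), PLAU (0.37) and SAMD9L (-0.25), hydrogen 3 for SOX9 (0.61), and silicon 3 for PMAIP1 (0.42) and SAMD9L (-0.30). A fit of only these groups ended the calls of SOX9, PMAIP1 and SAMD9L.

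Iron and hydrogen stand furthest apart in linear energy transfer. IFI6 and ISG15, both induced by interferon, were higher in iron, at 7.89 ± 0.975 against 4.01 ± 0.876 CPM (SD, n = 3) and 24.8 ± 4.01 against 14.6 ± 2.63. EGR1 (an immediate early transcription factor, ENSG00000120738, chromosome 5, 138465479 to 138469303) was higher, at 37.8 ± 0.964 against 23 ± 1.51 CPM, and SFRP1 at 29.3 ± 1.95 against 16 ± 0.611. KLF10 (a TGF-beta early response factor, ENSG00000155090, chromosome 8, 102648784 to 102655725) was lower, at 26.5 ± 1.84 against 47.8 ± 1.82 CPM, and BHLHE40 (a clock and hypoxia factor) at 22.3 ± 0.384 against 41.1 ± 0.334. ACAN, MGP (matrix Gla protein) and NTRK2 differed by -1.49, -0.82 and -0.81 (log2, SE up to 0.13). C1orf35 differed by 0.62 ± 0.17 and was not called with GC offsets. None of these genes had an edgeR adjusted p above 0.0464. GDF15 was the preset gene that differed (0.48 ± 0.11).

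Each list call between iron and hydrogen was lost with an estimated correlation. G2/M and mitosis genes moved down (camera adjusted p = 0.0145, adjusted p = 0.193 with an estimated correlation). Of 29 genes, 2 fell, and 6 fell adjusted over the list alone. ASPM and FOXM1 changed by -0.82 and -0.91 (log2, SE up to 0.24). By camera, secreted protease and inhibitor genes moved up (adjusted p = 0.0165, adjusted p = 0.0806 with an estimated correlation). Of 19 genes, 2 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone. MMP14 and TIMP3 changed by 0.28 and -0.24 (log2, SE up to 0.05). Collagen and matrix genes moved down (camera adjusted p = 0.0145, adjusted p = 0.488 with an estimated correlation). Of 30 genes, 3 fell, and 1 rose and 10 fell adjusted over the list alone. COL15A1 and VCAN changed by -0.60 and -0.33 (log2, SE up to 0.08). By camera, fibroblast markers moved down (adjusted p = 0.0145, adjusted p = 0.0806 with an estimated correlation). Of 14 genes, 3 fell, and 1 rose and 6 fell adjusted over the list alone. DCN and PRRX1 changed by -0.58 and -0.26 (log2, SE up to 0.07). EdgeR called 175 genes higher and 171 lower in iron, 9 by 2-fold or more. Log2 changes followed GC content across genes (rho = 0.699). With GC offsets, not tried on lists, 426 genes were called, of which 209 were among the 346. The count was 931 with no filter, 741 with the replicate block, 934 with the DESeq2 Wald test and 101 in a fit of only these groups. Single libraries decided it too: it was 82 without iron 1, 191 without iron 3, 85 without hydrogen 1, 84 without hydrogen 2 and 1740 without hydrogen 3. Calls ended without iron 1 for C1orf35 (0.41), FOXM1 (-0.85), MMP14 (0.24), VCAN (-0.29) and PRRX1 (-0.24), iron 3 for C1orf35 (0.67) and FOXM1 (-0.87), hydrogen 1 for C1orf35 (0.62), FOXM1 (-0.83), MMP14 (0.24), VCAN (-0.30) and PRRX1 (-0.23), hydrogen 2 for C1orf35 (0.60), FOXM1 (-0.97), MMP14 (0.24), VCAN (-0.31) and PRRX1 (-0.24), and iron 2 for FOXM1 (-1.04). A fit of only these groups ended the calls of C1orf35, ASPM, FOXM1 and PRRX1.

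Iron and silicon, the heavy ions, differed at few genes. EGR1 was higher in iron, at 37.8 ± 0.964 against 21.1 ± 0.946 CPM (SD, n = 3), as were JUN (another early gene), at 99.6 ± 9.01 against 71.6 ± 6.30, and IFI6, at 7.89 ± 0.975 against 4.18 ± 0.400. KLF10 was lower, at 26.5 ± 1.84 against 51.1 ± 1.13 CPM, and BHLHE40 at 22.3 ± 0.384 against 42.0 ± 1.20. TRERF1 and PPP1R10 differed by 0.50 and 0.42 (log2, SE up to 0.11). TFAP2C, KLF9 and SNAI2 (Slug, a factor of mesenchymal cells) differed by -0.61, -0.52 and -0.51 (log2, SE up to 0.12). Their edgeR adjusted p was at most 0.0327. Interferon-stimulated genes moved up (camera adjusted p = 2.02e-07). Of 22 genes, 1 rose, and 7 rose adjusted over the list alone. ISG15 changed by 0.50 (log2, SE 0.13), not called. The other camera call was contractile myofibroblast genes (adjusted p = 0.0152, adjusted p = 0.29 with an estimated correlation), upward in iron. MMP3 was the preset gene that differed (-0.32 ± 0.06). EdgeR called 8 genes higher and 29 lower in iron, 2 by 2-fold or more. Changes followed GC content across genes (rho = 0.592). With GC offsets, not tried on lists, 104 genes were called. It was 81 with no filter, 92 with the DESeq2 Wald test and 78 in a fit of only these groups. The count was 16 without silicon 2, 16 without silicon 3, 10 without iron 1, 15 without iron 2 and 20 without iron 3. Calls ended without silicon 1 for TRERF1 (0.42), silicon 3 for TRERF1 (0.46), JUN (0.40) and TFAP2C (-0.62), iron 1 for TRERF1 (0.53), JUN (0.40) and TFAP2C (-0.65), iron 2 for TRERF1 (0.44) and TFAP2C (-0.52), iron 3 for TRERF1 (0.50), and silicon 2 for TFAP2C (-0.54). A fit of only these groups ended the call of TRERF1.

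The gamma effect was then compared with each ion effect as a difference of changes, gamma minus ion. ACAN, which fell by 6.29 on the log2 scale under silicon and by 0.37 under gamma, differed by 5.92 ± 0.13 (SE, n = 3 per group). ITGA8, COLEC12, C1R and SAPCD2 (a spindle protein) differed from silicon by 2.95, 2.77, 2.77 and 2.94 (log2, SE up to 0.58). MMP1, MMP10, CD24 and MMP3 differed by -4.11, -3.76, -3.32 and -2.40 (log2, SE up to 0.29). These genes had an edgeR adjusted p of up to 0.000353.

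Higher by camera in the gamma effect were contractile myofibroblast genes (adjusted p = 2.52e-19) and collagen and matrix genes (adjusted p = 3.48e-12). So were, by camera, G2/M and mitosis genes (adjusted p = 7.99e-05) and fibroblast markers (adjusted p = 0.00106). Lower in camera were secreted protease and inhibitor genes (adjusted p = 2.76e-10), cholesterol synthesis genes (adjusted p = 5.28e-06) and replication-dependent histone genes (adjusted p = 0.000512). ACTA2, LMOD1, COL15A1 and THBS2 differed by 1.57, 1.0, 2.29 and 0.84 (log2, SE up to 0.11). Higher in camera, but lost, were immediate early genes (adjusted p = 0.017, adjusted p = 0.425 with an estimated correlation). Lower in camera, but lost, were lysosome and mitochondrially encoded genes (adjusted p = 0.0183 and 0.034, with an estimated correlation 0.201 and 0.562). EdgeR called 1284 genes higher and 1312 lower in the gamma effect. The arms differ in more than radiation, as their controls differ at most genes. G2/M genes were higher in the gamma control by a median of 5.08 (log2). Their falls under ions started low and cannot rank ions against gamma.

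Against iron, ACTC1, ACAN, C1R, NIPAL4 and TMEM119 (an osteoblast membrane protein) differed by 3.0, 6.09, 2.92, 2.89 and 2.88 (log2, n = 3 per group, SE up to 0.22). MMP1, MMP10, CD24 and MMP3 differed by -3.96, -3.49, -3.08 and -2.09 (log2, SE up to 0.29). FOXM1, MKI67, ACTA2 and ITGA11 differed by 2.10, 1.93, 1.49 and 1.13 (log2, SE up to 0.28). EdgeR gave each gene named here an adjusted p of 5.35e-06 or less. Higher in camera than under iron were contractile myofibroblast genes (adjusted p = 1.6e-16) and collagen and matrix genes (adjusted p = 2.37e-12). So were, by camera, G2/M and mitosis genes (adjusted p = 3.13e-05) and fibroblast markers (adjusted p = 0.000554). Lower in camera than under iron were secreted protease and inhibitor genes (adjusted p = 5.66e-10), cholesterol synthesis genes (adjusted p = 4.9e-06) and replication-dependent histone genes (adjusted p = 0.000554). Higher than under iron in camera, but lost, were immediate early genes (adjusted p = 0.035, adjusted p = 0.541 with an estimated correlation). Lower than under iron in camera, but lost, were lysosome, mitochondrially encoded and oxidative stress response genes (adjusted p = 0.0105, 0.0339 and 0.0467). With an estimated correlation their adjusted p was 0.17, 0.584 and 0.256. EdgeR called 1376 genes higher and 1375 lower in the gamma effect.

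Against hydrogen, whose linear energy transfer was the lowest of the ions, ACAN, ACTC1, C1R, TSPOAP1 (a mitochondrial receptor adaptor) and SAPCD2 differed by 4.61, 2.46, 2.31, 2.54 and 2.42 (log2, n = 3 per group, SE up to 0.51). MMP1, MMP10, CD24 and MMP3 differed by -3.77, -3.36, -2.95 and -2.14 (log2, SE up to 0.29). ACTA2, ITGA11, COL15A1 and THBS2 differed by 1.48, 1.0, 1.62 and 0.75 (log2, SE up to 0.11). None of these genes had an edgeR adjusted p above 0.0011. Higher in camera than under hydrogen were contractile myofibroblast genes (adjusted p = 2.25e-19) and collagen and matrix genes (adjusted p = 1.23e-11). So were, by camera, fibroblast markers (adjusted p = 0.0117). Lower in camera than under hydrogen were secreted protease and inhibitor genes (adjusted p = 1.27e-08), cholesterol synthesis genes (adjusted p = 1.34e-05) and replication-dependent histone genes (adjusted p = 0.00382). Higher than under hydrogen in camera, but lost, were immediate early genes and G2/M and mitosis genes (adjusted p = 0.000646 and 0.0115). With an estimated correlation their adjusted p was 0.277 and 0.18. Lower than under hydrogen in camera, but lost, were mitochondrially encoded genes (adjusted p = 0.0115, adjusted p = 0.493 with an estimated correlation), secreted growth factor and IGF-binding genes (adjusted p = 0.0352, adjusted p = 0.0705 with an estimated correlation) and secretory cytokine and chemokine genes (adjusted p = 0.0377, adjusted p = 0.0705 with an estimated correlation). EdgeR called 1008 genes higher and 1128 lower in the gamma effect.

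The controls were compared to show how far shipped, unirradiated cells stood from low passage cells. The low passage libraries differed most among themselves, with a chi-square per gene of 29.1, 13.2 and 15.3 between pairs, above the pairs of any other group. In the particle control, IL33 (an alarm cytokine, ENSG00000137033, chromosome 9, 6215786 to 6257983) was at 0.149 ± 0.0965 against 242 ± 14.5 CPM (SD, n = 3) in the low passage cells. CXCL8 was at 0.172 ± 0.0350 against 77.3 ± 9.25 and TM4SF1 (a surface protein) at 1.60 ± 0.253 against 384 ± 47.7. MMP1 was at 2.67 ± 0.327 against 266 ± 35.5 and CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687337) at 2194 ± 47.8 against 470.1 ± 52.9. Their edgeR adjusted p was at most 2.27e-23.

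Lower in the particle control than in the low passage cells were, by camera, DNA replication and G1/S genes (adjusted p = 5.85e-19), G2/M and mitosis genes (adjusted p = 4.59e-12) and homologous recombination and Fanconi genes (adjusted p = 3.41e-10). By camera, secreted protease and inhibitor genes (adjusted p = 3.44e-08), nuclear lamina and chromatin genes lost in senescence (adjusted p = 2.5e-07) and secretory cytokine and chemokine genes (adjusted p = 2.83e-06) were lower as well. By camera, unfolded protein and amino acid response genes (adjusted p = 0.000122) were lower as well. Higher by camera were contractile myofibroblast genes (adjusted p = 9.75e-13), p53 target genes (adjusted p = 1.54e-06) and replication-dependent histone genes (adjusted p = 0.0117). MKI67, CDC20, CDC6 and RRM2 changed by -3.16, -3.56, -4.48 and -4.37 (log2, SE up to 0.15). LMOD1, ACTA2, CDKN1A and PLK2 rose by 3.30, 2.21, 2.22 and 1.16 (log2, SE up to 0.07). Higher by camera, but lost, were collagen and matrix genes, lysosome genes and pericyte and smooth muscle markers (adjusted p = 2.29e-05, 0.0465 and 0.0466). With an estimated correlation their adjusted p was 0.163, 0.202 and 0.142. Lower by camera, but lost, were immediate early and heat shock genes (adjusted p = 1.47e-08 and 0.0466, with an estimated correlation 0.0511 and 0.163). EdgeR called 5329 genes higher and 5111 lower in the particle control, 3707 by 2-fold or more. Shipping, passage number and time in culture differ together here.

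The gamma control stood apart from the low passage cells partly as the particle control did (IL33, contractile genes) and partly not (MKI67, G2/M genes). MKI67 was at 132 ± 5.72 against 13.9 ± 1.76 CPM (SD, n = 3) and CCNB1 (cyclin B1) at 121 ± 1.64 against 14.6 ± 1.12. RARB (a retinoic acid receptor, ENSG00000077092, chromosome 3, 24687887 to 25597932) was at 18.7 ± 0.532 CPM against no count in the low passage cells. IL33 was at 0.0243 ± 0.0421 against 242 ± 14.5. These genes had an edgeR adjusted p of up to 8.74e-21.

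Higher in the gamma control than in the low passage cells were, by camera, G2/M and mitosis genes (adjusted p = 4.94e-24), contractile myofibroblast genes (adjusted p = 3.2e-06) and interferon-stimulated genes (adjusted p = 4.76e-05). By camera, nuclear lamina and chromatin genes lost in senescence (adjusted p = 0.000981) and p53 target genes (adjusted p = 0.00393) were higher as well. By camera, lower were secreted protease and inhibitor genes (adjusted p = 9.03e-15), secreted growth factor and IGF-binding genes (adjusted p = 0.000138) and cholesterol synthesis genes (adjusted p = 0.0117). By camera, secretory cytokine and chemokine genes (adjusted p = 0.019) and DNA replication and G1/S genes (adjusted p = 0.0268) were lower as well. Lower by camera, but lost, were immediate early and mitochondrially encoded genes (adjusted p = 1.91e-07 and 0.000981, with an estimated correlation 0.0686 and 0.326). Mitochondrial genes held 3.46 ± 0.390% of counts (SD, n = 3) in the gamma control, 3.66 ± 0.214% in gamma and 5.11 ± 0.631% in the low passage cells. EdgeR called 5110 genes higher and 4929 lower in the gamma control, 3262 by 2-fold or more.

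The last comparison sets the shipped, unirradiated controls against each other, gamma against particle. MKI67 was at 132 ± 5.72 against 1.57 ± 0.323 CPM (SD, n = 3). The mitotic genes TROAP and DLGAP5 were at 20.8 ± 1.62 against 0.184 ± 0.0702 and 49.8 ± 2.09 against 0.526 ± 0.165. MMP1 was at 203 ± 5.61 against 2.67 ± 0.327 and IL6 at 24.1 ± 0.339 against 2.97 ± 0.0630. CDKN1A was at 782 ± 38.7 against 2194 ± 47.8 and PLXDC2 at 0.131 ± 0.0765 against 11.7 ± 1.76. EdgeR gave each of these genes an adjusted p of 6.22e-19 or less.

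Higher in the gamma control than in the particle control were, by camera, G2/M and mitosis genes (adjusted p = 3.52e-30), DNA replication and G1/S genes (adjusted p = 2.99e-23) and nuclear lamina and chromatin genes lost in senescence (adjusted p = 7e-14). By camera, homologous recombination and Fanconi genes (adjusted p = 4.23e-11), unfolded protein and amino acid response genes (adjusted p = 3.65e-05) and interferon-stimulated genes (adjusted p = 0.000142) were higher as well. By camera, secretory cytokine and chemokine genes (adjusted p = 0.000172) were higher as well. Lower in the gamma control by camera were contractile myofibroblast genes (adjusted p = 1.22e-07), lysosome genes (adjusted p = 0.00032) and cholesterol synthesis genes (adjusted p = 0.00143). By camera, p53 target genes (adjusted p = 0.00156), secreted protease and inhibitor genes (adjusted p = 0.00187) and replication-dependent histone genes (adjusted p = 0.019) were lower as well. By camera, secreted growth factor and IGF-binding genes (adjusted p = 0.0231) were lower as well. RRM2, FANCI, LMNB1 and HMGB2 rose by 5.45, 2.54, 4.35 and 3.01 (log2, SE up to 0.12). Higher in camera between the controls, but lost, were immediate early genes (adjusted p = 0.000793, adjusted p = 0.23 with an estimated correlation). Lower in camera between the controls, but lost, were collagen and matrix genes (adjusted p = 2.93e-06, adjusted p = 0.105 with an estimated correlation). EdgeR called 4418 genes higher and 4598 lower in the gamma control, 2670 by 2-fold or more. The labels do not say what set the culture histories of these controls apart.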

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

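The tests with DESeq2 size factors, on genes on or off in the gamma arm, on hydrogen as a low energy transfer ion, on swapped labels and on the calls shared by the ions were chosen only after the result was seen, as were the make-up of the splits and all counts of other splits except those for gamma against iron and against hydrogen.

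Effects of 2 groups differed by a direct test in 6 comparisons, given with calls among 14 preset genes and, in brackets, the lists that stood in camera with an estimated correlation. MMP1 and MMP3, higher in silicon than in hydrogen, belong to a difference of 83 genes, 9 lists (5) and 2 preset genes. GDF15 belongs to 346 genes, 4 lists (0) and 1 preset gene that differed between iron and hydrogen, and MMP3 to 37 genes, 2 lists (1) and 1 preset gene between iron and silicon. For the gamma effect against the effects of silicon, iron and hydrogen, ACAN and ACTA2 among the genes, the counts were 2596 genes, 10 lists (7) and 9 preset genes, 2751 genes, 11 lists (7) and 8 preset genes, and 2136 genes, 11 lists (6) and 8 preset genes.

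Other splits of the 6 libraries of each pair of ions, of an ion or gamma and its control, or of 2 controls number 10, too few for a share under 5%. The real split and the highest other split called 4360 and 0 genes for silicon, 4295 and 1 for iron, 3906 and 0 for hydrogen, 131 and 0 for gamma, 83 and 0 for silicon against hydrogen, 346 and 0 for iron against hydrogen, 37 and 0 for iron against silicon, and 10440, 10039 and 9016 against 0 for the controls. In lists such as the contractile genes, they were 11 and 9 for silicon, 9 and 9 for iron (with 3 of the 10 splits as high), 11 and 6 for hydrogen, 10 and 6 for gamma, 9 and 3, 4 and 2, and 2 and 1 between ions in the same order, and 15 and 14, 12 and 9, and 16 and 15 between controls, with 1 split as high in each unless said. For the gamma effect against silicon, iron and hydrogen, 100 splits were drawn, and 1 of 100 called as many genes (the real one, highest other 2460, 2499 and 2099). The share cannot exclude chance for a difference between gamma and an ion, since the count followed the grouping of the ion libraries. The 7 splits that kept the ion libraries together and mixed gamma with its control called 2360 to 2460, 2200 to 2499 and 1682 to 2099 genes, and the others at most 8. For either arm alone the groupings are too few for a share under 5%. As many lists passed in 8, 5 and 6 of 100 splits (highest other 13, 13 and 14), so chance cannot be excluded for the list counts.

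The shipped, unirradiated controls differed at 9016 genes, MKI67, MMP1 and CDKN1A among them. DESeq2 size factors gave 9002 calls. Like TMM factors, they are little moved by a few abundant genes, so this count cannot decide on scaling. Unequal depth is argued against by 8547 calls with all libraries thinned to 1 total. Cells of another source in the gamma arm stay possible: 2 genes were on in all libraries of that arm and off in all others. Any other pair of groups had 0, but no other pair makes up a whole arm, so that is no yardstick. The minimum of 10 such genes for a decision was set after the count of 2 was seen, so this test leaves the source open. Culture state, which MKI67 reports, also differs between the arms and was not tested.

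Gamma rays changed 131 genes against 3906 for hydrogen, and neither CDKN1A nor LMNB1 was called under gamma. The counts were 341 and 4401 with GC offsets, 238 and 4285 in fits of only the groups compared, and 203 and 4023 with the DESeq2 Wald test. With all libraries thinned to 1 total gamma had 133 calls and hydrogen 3643, which argues against depth. A swap of labels within the gamma arm is argued against by the highest other split, which called 0 genes in edgeR. Hydrogen had 3906 calls at a low linear energy transfer of 0.5 keV/µm, but that count is part of the pattern and rests on the particle control, so the role of linear energy transfer stays open. A particle control that stands apart for reasons other than radiation could raise the counts of all 3 ions, which share it and 1447 rises and 1210 falls (2657 genes); the design has no other control of that arm, so this cannot be told apart from an effect common to the ions. A smaller response of cells that were cycling, as the gamma arm was, stays open and untested.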

How the results depend on the processing

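The GC offsets were chosen only after the data were seen; the other alternatives were planned. Of the 482 changes of named genes, such as MMP1 and ACAN, 480 kept direction and side of the threshold with DESeq2 size factors, 477 with no filter, 480 with the replicate block, 466 with GC offsets and 470 with the DESeq2 Wald test, and none of them reversed there. The calls lost were SAMD9L in silicon against hydrogen with DESeq2 size factors, IL6 in silicon with no filter and C1orf35 in iron against hydrogen with GC offsets. Of 480, 477 kept both with a filter of 1 CPM in 3 libraries and 458 in fits of only the groups compared. Those fits ended the calls of IL6 in silicon, SOX9, PMAIP1 and SAMD9L in silicon against hydrogen, C1orf35, ASPM, FOXM1 and PRRX1 in iron against hydrogen and TRERF1 in iron against silicon, at an edgeR adjusted p from 0.0555 to 0.128. Leaving out 1 library in turn kept 3324 of 3420, with 89 no longer called, 7 newly called and none reversed. Of 131 list calls in 338 tests, 83 stood with an estimated correlation and 48 were lost; with fry 85 lists were newly called, 8 lost and 1 reversed, the fibroblast markers in the particle control against low passage cells (adjusted p = 6.29e-07 by fry, with the camera call not past the threshold). With the replicate block 1 list was lost. Same-number libraries were not correlated beyond 0.1 at all 3 numbers in any contrast, so the block has no basis in the data.

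Counts of called genes moved by more than 1.5 times in these cases, and the cause was not tested. With no filter they were 139 for silicon against hydrogen, 931 for iron against hydrogen and 81 for iron against silicon. With the replicate block the iron against hydrogen count was 741. With GC offsets the counts were 341 for gamma, 225 for silicon against hydrogen and 104 for iron against silicon. The DESeq2 Wald test gave 203 for gamma and, between ions in the same order as above, 141, 934 and 92. Fits of only the groups compared, which have fewer libraries to estimate the spread, gave 238 for gamma, 101 for iron against hydrogen and 78 for iron against silicon. Another control gave 10057, 9832 and 10087 for silicon, iron and hydrogen with the gamma control, 10555, 10600, 10573 and 9767 for silicon, iron, hydrogen and gamma with the low passage cells, and 8753 for gamma with the particle control. The 28 genes called by all 4 radiations became 2 with a 2-fold minimum and 78 with GC offsets, and the 2657 called by all 3 ions became 386 with a 2-fold minimum.

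Leaving out 1 library in turn, called genes ranged from 3510 to 3698 for silicon, 3455 to 3639 for iron, 2892 to 4312 for hydrogen, 75 to 96 for gamma, 39 to 108 for silicon against hydrogen, 82 to 1740 for iron against hydrogen and 10 to 26 for iron against silicon. For the gamma effect against silicon, iron and hydrogen they ranged from 2167 to 2372, 2269 to 2535 and 1690 to 2476, for the controls in the order of the report from 9826 to 10289, 9345 to 10010 and 8268 to 8353, and for genes shared by all 4 radiations and by all 3 ions from 23 to 28 and 2142 to 2657. The report gives the libraries behind counts beyond 1.5 times of the main one.

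Directions reversed under another control, and the cause was not tested. With the gamma control as the control, the log2 changes under silicon were MMP1 -2.47, CDKN1A 1.20, IL6 -2.63, CXCL8 -0.99, COL15A1 0.37 and ACTG2 1.31, under iron MMP1 -2.62, CDKN1A 1.28, CDKN2B 2.19, IL6 -2.31, CXCL8 -1.51, COL15A1 0.43, ITGA11 0.21, CTSL -0.23 and ACTG2 1.51, and under hydrogen MMP1 -2.81, SORBS2 0.18, CDKN1A 1.10, IL6 -2.21, CXCL8 -1.62, COL15A1 1.03, ACTG2 1.34 and LMOD1 0.021.

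With the low passage cells as the control, the reversed log2 changes under silicon were MMP10 -0.26, MMP1 -2.87, MMP3 -1.38, SORBS2 1.75, ACTC1 1.55, CDKN1A 1.94, IL6 -2.73, CXCL8 -6.57, THBS2 0.11, ACTA2 0.82, LMOD1 2.29, ACTG2 0.33, MT-ND1 -0.18, PDGFRA -0.45, MCAM 1.5, LPXN -0.18 and GAS1 2.02. Under iron they were MMP10 -0.52, MMP1 -3.01, ACTC1 1.31, SORBS2 1.70, CDKN1A 2.02, CDKN2B 2.52, IL6 -2.42, CXCL8 -7.09, MMP3 -1.69, THBS1 0.56, ACTA2 0.90, LMOD1 2.35, ITGA11 0.95, CTSL -0.89, MT-ND1 -0.19, PDGFRA -0.55, LPXN -0.32, GAS1 2.24 and ACTG2 0.54. Under hydrogen they were MMP10 -0.66, MMP1 -3.21, MMP3 -1.64, ESM1 -3.26, SORBS2 2.0, ACTC1 1.86, CDKN1A 1.83, IL6 -2.31, CXCL8 -7.20, ANGPTL4 -1.17, ACTA2 0.91, ACTG2 0.36, LMOD1 2.47, MT-ND3 -0.039, MT-ND2 -0.083, MCAM 1.5, LPXN -0.32 and GAS1 2.48. Under gamma they were COMP -1.18, ATF3 -0.40, COL15A1 -3.38, TGFBI -0.19, WNT2 1.65, TNFRSF19 2.21, CDKN1A 0.72, CDKN2A -0.60, LMNB1 0.92, HMGB2 1.70, MKI67 3.17, CXCL8 -5.38, MMP3 -3.48, RRM2 0.88, TYMS 1.02, ASPM 2.69, PLK1 3.93, AURKA 1.21, LMNB2 0.89, HMGB3 0.75, MMP2 -0.95, SERPINE2 -1.58, TIMP3 -2.23, TNC -0.14, EGR1 -0.60, ZFP36 -0.54, DUSP1 -0.85, FAP -0.72, PDGFRA -1.07, NOTCH3 0.67, NTM -2.55, LPXN -0.90, ACAN 3.75, GAS1 2.64 and TENM2 1.28.

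With the particle control as the control of gamma, the reversed log2 changes were COMP -1.44, COL15A1 -1.05, WNT2 1.69, TNFRSF19 1.67, CDKN2A -1.01, CDKN2B -2.08, LMNB1 4.32, HMGB2 2.94, MKI67 6.33, GDF15 -1.0, MMP1 5.91, RRM2 5.25, TYMS 3.66, ASPM 4.35, PLK1 4.88, AURKA 2.77, LMNB2 1.60, CBX5 0.93, HMGB3 0.74, MMP2 -0.82, SERPINE2 -0.96, TIMP3 -0.39, VCAN -0.36, FAP -1.08, NTM -1.41, ACAN 1.25 and TENM2 1.5. Depth limits genes near the floor: at 19296278 counts in the smallest library, genes under 1 CPM such as CXCL8 rest on few counts per library.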

Other observations

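The counts with no library shared were chosen only after the result was seen. From the low passage cells to the particle control, ACTA2 rose from 466 ± 33.6 to 2159 ± 29.5 CPM (SD, n = 3) and MMP1 fell from 266 ± 35.5 to 2.67 ± 0.327. In silicon, iron and hydrogen ACTA2 stood at 819.6 ± 20.2, 871 ± 14.4 and 876 ± 29.9 and MMP1 at 36.5 ± 1.16, 33.1 ± 2.70 and 28.8 ± 1.11. Other genes moved further away: COL15A1 went from 205 ± 14.8 to 41.0 ± 0.251 and then to 14.7 ± 0.321, 15.3 ± 1.28 and 23.3 ± 1.84. Of the 2657 genes changed the same way by all 3 ions, 2174 also differed between the particle control and the low passage cells, 1286 in the opposite direction and 888 in the same. These comparisons share the control group, so counts with no library shared do not remove a deviation common to it.

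The pattern was noticed in the means of ACTA2, MMP1 and other named genes. Ion effects ran weakly opposite to the change from low passage cells to the particle control across 9349 genes, which are not independent. Noise of a shared control library would give such a correlation. With no library shared the highest of 9 was -0.109, which argues against that as the whole cause. A deviation common to the control group would still give it. With GC offsets the highest mean correlation was -0.123, which argues against a GC trend. What lies behind the pattern stays open and was not tested, since genes such as COL15A1 go against it and passage and shipping differ together in that control.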
